A study of Populus trichocarpa with 12 samples.

How the data were processed

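ChIP-seq libraries of H3K9ac immunoprecipitates and of input DNA came from differentiating stem xylem of Populus trichocarpa at day 0, day 5 and day 7 without water, with 2 replicates of each kind per day. Per the labels' protocols, chromatin was sonicated to 200 to 1000 bp, and libraries of about 250 bp fragments were amplified over 18 PCR cycles. The submitters' processing notes name Bowtie as a tool, and its version and the filters on reads are not given in the sources used here. PCR reads carry no molecular identifiers, so read numbers are not numbers of independent molecules.

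The deposited files are 2 tables of differential regions, day 5 against day 0 and day 7 against day 0. Per the file headers, they were made with diffReps 1.55.4, with a negative binomial test on windows of 1000 bp moved by 100 bp, a fragment length of 100 bp, a window p-value threshold of 0.0001, a right-trimmed mean with an alpha of 0.05 and a deviation threshold of 2. Each table lists only windows that passed this threshold, merged into regions. The normalised read signal of both libraries of each group stands in a single cell, separated by a semicolon, in the order of libraries that the headers give, per the file headers. The deposited average signal per group is the mean of these normalised reads. The deposited ratio columns hold the fold enrichment of each group over its background. The deposited log2 column is the log2 fold change of drought over day 0, taken from the immunoprecipitated libraries alone. The deposited p-value columns hold the region p-value and its Benjamini-Hochberg adjustment, per the file headers over 59188 tests at day 5 and 57991 at day 7. How that test estimates the spread between libraries is not given in the sources used here. Per the file headers, the day 0 inputs were the background of the drought libraries and the drought inputs the background of the day 0 libraries. In the 593 regions of identical coordinates in both tables, the background implied for the drought libraries differed between the tables by a median of 0.00333 on the log2 scale and that for day 0 by 0.318, as such an arrangement gives. For the classes of enrichment it was therefore recomputed as the geometric mean of both groups over both inputs.

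The genome build is not named in full in the sources used here. The gene table at hand belongs to assembly P.trichocarpa_v4.1, and 214 regions at day 5 and 245 at day 7, on 13 chromosomes, began past the last gene of their chromosome in it, so genes were not assigned. The comparisons of gene lists, of positions relative to genes and of the abscisic acid response motif that had been planned were not run, and no count of genes is given. Named regions follow the rule fixed for genes, without its condition that a gene is assigned. Among regions past an adjusted p of 0.05 with at least 20 normalised reads in the larger group, these were the 10 highest and the 10 lowest log2 fold changes per day, and the 5 gained and 5 lost on both days with the largest smaller change. The groups, the comparisons, this rule and the main list of other settings were set before the data were examined.

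Normalised values multiplied by a constant per library, fitted near the normalisation constant in the header, came out whole within 0.1 in 100% of regions for every library, and in between 19.7% and 21.7% with the constant of the other library. Reads per library in the listed regions, with a smallest value of 62 reads, were taken from these products. The right-trimmed mean of reads per 1000 bp bin was 94.3 and 64.7 for the day 5 libraries, 75.8 and 78.1 for day 0, and 60.4 and 79.2 for day 7, per the file headers. Inputs are read in the tables through the background ratio and their depth is unknown. Changes of the input are therefore given relative to the median listed region of each comparison. The reads of day 0 were identical in both tables in 593 of 593 shared regions. These totals cover listed regions alone and are not library depths.

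The count of gained and lost regions follows the adjusted p of the authors' deposited table. The columns hold normalised values, and the count model planned for per-library counts was not fitted to the recovered reads. In its place limma 3.58.1 in R 4.3.3 was run on log2 of the normalised reads. It used no pseudocount, a trended prior variance and Benjamini-Hochberg adjustment over the listed regions. Printed log2 changes, standard errors and adjusted p-values of single regions come from this limma fit, and means and SDs from the normalised reads of 2 libraries per group. Regions were listed because the same libraries differed, so these p-values are smaller than in an unselected set. Day 7 was compared with day 5 in a limma fit of all 6 immunoprecipitated libraries over the 593 regions of identical coordinates, on the scale of the day 5 table. With 2 libraries per group an exact permutation test of a single region cannot reach 0.05, and none was run.

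Counts were simulated from the day 0 means and depths of the real libraries, with a single dispersion for all regions and 200 regions changed. On them, the limma step was tested for both comparisons with day 0. At day 5 it recovered 27.9%, 90.9% and 100% of log2 changes of 0.3, 0.5 and 1, with 5 false calls among 150. At day 7 it recovered 57.4%, 98.5% and 100%, with 14 false calls among 184. In the real regions limma called 8884 at day 5 and 10091 at day 7, far more than were changed here. These shares and false calls therefore do not give its recovery or its rate of false calls in the listed regions. For day 7 against day 5, log2 values were simulated with normal noise of a single SD per day, with 200 of 593 regions changed. There limma recovered 48.5%, 90.9% and 100%, with 7 false calls among 166. In the real regions this comparison called 0, so these shares do not give its recovery there either. Agreement between days was set beside 100 simulations of unchanged groups against shared day 0 libraries and beside independent lists of the same covered length. Neighbouring directions were tested with 100000 permutations, and the share of gained regions per chromosome with an exact test over all circular shifts of the directions along the genome, two-sided. Overlap needed at least 1 bp. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives were an adjusted p of 0.001, a log2 change of at least 1, a minimum of 20 normalised reads, a deposited enrichment of at least 2 in the group with more reads, unscaled reads, a replicate block, each replicate left out, a shared length of at least 50% and centring of each day, with further ones added after the data were seen.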

Results

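H3K9ac, the acetylation of lysine 9 on histone H3 that marks active promoters in plants, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in differentiating stem xylem, the wood-forming tissue, of black cottonwood (Populus trichocarpa). Plants were 3 months old and were watered throughout (day 0) or left without water for 5 days (day 5) or 7 days (day 7). The labels give a soil water content of 74% at day 0, 33% at day 5 and 29% at day 7, and a xylem water content of 80.6%, 75.3% and 74.3%. Each day had 2 immunoprecipitated libraries and 2 input libraries, so that 12 samples formed 6 groups. The labels do not say whether replicates came from separate plants, so the p-values measure the spread between these samples, which may be technical. They name no sequencing batch. Day 0 is the only watered group, and neither drought day has a watered group of its own. An effect of drought can therefore not be told apart from other differences between the groups, such as time or handling. The reads that fell within the listed regions numbered 5813447 and 4017187 for the day 5 libraries, and 5156357 and 5232391 for the day 0 libraries over the same regions. In the day 7 comparison they numbered 3862141 and 4869871 for day 7, and 5458767 and 5553556 for day 0. The median region held between 256 and 435 reads per library. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom of 3.25 at day 5, 2.01 at day 7, and 1.88 and 1.42 at day 0 over the regions of the 2 tables.

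Mild drought was compared with watered plants to ask where H3K9ac changed when soil water first fell. In the authors' deposited table, 9706 of 10605 listed regions passed an adjusted p of 0.05 at day 5, of which 4591 were gained (47.3%) and 5115 were lost. Most changes were modest. The median gained region in the authors' deposited table held 1.36 times the day 0 reads (log2 0.44), and the median lost region held 0.742 times (log2 -0.43). Log2 fold changes in the authors' deposited table ran from -1.61 to 1.61, with 92 gained and 84 lost regions past a log2 change of 1. The listed regions covered 16319 kb, with a median length of 1300 bp. The libraries of the regions were also compared with limma, which called 8884 regions at an adjusted p of 0.05, and 86.5% of the regions called in the authors' deposited table were among them. These regions had been listed because the same libraries differed, so limma adds no independent evidence. The larger share turned to gained regions at a recomputed enrichment over input of at least 2, with 2719 gained and 1509 lost, and at a deposited enrichment of at least 2, with 2921 and 2683. Without day 0 replicate 1, limma called 2836 gained and 3166 lost regions, and without day 0 replicate 2 it called 3026 and 3200.

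The largest gains at day 5 were 2.55-fold to 3.05-fold across 10 regions, and the largest losses were 2.40-fold to 3.06-fold across 10 regions. Coordinates are 1-based, in the build of the deposited files, and genes were not assigned to them. The region on chromosome 5 from 21194501 to 21198100 rose from 542 ± 14.2 normalised reads at day 0 to 1651 ± 93.5 at day 5 (SD, n = 2 each), a log2 change of 1.61 (SE 0.07, limma adjusted p = 0.00029). A region on chromosome 15 from 1334401 to 1337400 rose from 393 ± 88.6 to 1126 ± 150 normalised reads (SD, n = 2 each), a log2 change of 1.53 (SE 0.16, limma adjusted p = 0.00053). On chromosome 1, the region from 33770301 to 33772900 rose from 406 ± 14.5 to 1097 ± 66.4 normalised reads (SD, n = 2 each; limma adjusted p = 0.00029). On chromosome 10, the region from 9919301 to 9921400 rose 2.55-fold, from 291 ± 1.36 to 742 ± 1.32 normalised reads (SD, n = 2 each). Among the lost regions, chromosome 17 from 5411201 to 5414100 fell from 1049 ± 15.8 to 410 ± 36.1 normalised reads (SD, n = 2 each), a log2 change of -1.36 (SE 0.08, limma adjusted p = 0.0003). Chromosome 2 from 13810701 to 13814300 fell from 1455 ± 24.2 to 606 ± 44.6 normalised reads (SD, n = 2 each; limma adjusted p = 0.0003). As a ratio, and among the named regions, the day 5 replicates differed most on chromosome 5 from 5764001 to 5766000, at 300 and 159 normalised reads against 579 and 575 at day 0, where the log2 change was -1.40 (SE 0.25, limma adjusted p = 0.0025).

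Severe drought was compared with the same day 0 libraries to ask where H3K9ac differed after 7 days. In the authors' deposited table, 10785 of 12101 listed regions passed an adjusted p of 0.05, with 5339 gained (49.5%) and 5446 lost. Median changes in the authors' deposited table were 1.33-fold for gained regions (log2 0.41) and 0.763-fold for lost regions (log2 -0.39). Its log2 fold changes ran from -1.52 to 1.57 in the authors' deposited table, and 110 gained and 81 lost regions passed a log2 change of 1. The listed regions covered 17849 kb, and their median length was 1200 bp. Of the regions that the authors' deposited table calls, limma called 85.9%, again over regions selected on the same libraries. Unscaled reads leave out the normalisation constants, 0.79 and 1.00 for day 7 against 1.11 and 1.13 for day 0, and so lower day 7 throughout. They put 3453 of the called regions above day 0 (32.0%), 7301 below and 31 at the same value. The right-trimmed means per bin were 60.39 and 79.25 against 75.9 and 78.25, so the constants do not follow these means alone. The near-even share of gained regions at day 7 therefore rests on the scaling. At a recomputed enrichment over input of at least 2, 1871 were gained and 1822 were lost, and at a deposited enrichment of at least 2, 2484 and 3493.

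At day 7 the 10 largest gains were 2.64-fold to 2.98-fold and the 10 largest losses 2.49-fold to 2.87-fold. The region on chromosome 10 from 1551101 to 1553400 rose from 220 ± 14.9 to 655 ± 78.6 normalised reads (SD, n = 2 each), a log2 change of 1.57 (SE 0.09, limma adjusted p = 7.7e-07). The region on chromosome 17 from 10097501 to 10100500 rose from 394 ± 33.6 to 1145 ± 38.3 normalised reads (SD, n = 2 each), a log2 change of 1.54 (SE 0.08, limma adjusted p = 6.6e-07). Chromosome 9 held strong changes of both kinds. Its region from 8822601 to 8825600 rose from 446 ± 12.9 to 1268 ± 10.8 normalised reads (SD, n = 2 each), and its region from 2006201 to 2009100 fell from 816 ± 2.03 to 316 ± 6.48 (SD, n = 2 each), both with a limma adjusted p of 6.6e-07. Chromosome 12 from 4361401 to 4365900, 4500 bp long, fell from 1803 ± 83.9 to 710 ± 40.8 normalised reads (SD, n = 2 each), a log2 change of -1.34 (SE 0.08, limma adjusted p = 7.3e-07). A gain on chromosome 17 from 3917401 to 3918600, at 261 and 429 normalised reads against 126 and 130 at day 0 (log2 1.38, SE 0.17, limma adjusted p = 3.4e-05), stood in a region whose input was also higher at day 7 by 2.36 on the log2 scale, and relative to the input its log2 change was -0.98.

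Whether the changes of mild drought were still present at severe drought was asked by overlapping the regions of both days. Of the day 5 regions called in the authors' deposited table, 5643 (58.1%) shared at least 1 bp with a called day 7 region, and 5709 day 7 regions (52.9%) shared at least 1 bp with a day 5 region. Of the 5856 overlapping pairs, 2240 were gained on both days, 3063 were lost on both days and 553 (9.44%) went in opposite directions. With a shared length of at least 50% of each region, 260 pairs (5.25%) went in opposite directions. Gained regions of the 2 days shared 3384 kb, against 960 kb for independent lists, and lost regions shared 4651 kb against 1134 kb. Both days were compared with the same day 0 libraries, which alone raises such agreement. In 100 simulations of 57991 unchanged windows against shared controls, 5.66 windows on average were called at day 5 and 0 on both days. So few simulated calls say little of how far shared controls raise the overlap of the listed regions, and part of the excess may come from them. Fold changes of the overlapping pairs in the authors' deposited table correlated across regions, which are not independent replicates, at r = 0.902 (Spearman's rho 0.892). In the 593 regions with identical coordinates the correlation was 0.971, and 583 of them (98.3%) had a single direction on both days. In simulated sets of the same size with no effect, drawn without selection, the correlation was 0.250. The covariance of the fold changes was 0.321, against 0.00342 in the simulations, a difference of 0.318. The observed regions were selected for a change on both days and the simulated ones were not, so these differences hold for the listed regions alone. When each day was set against a different day 0 library, with 1 library each, the correlation was 0.949 or 0.954. These regions had been listed with both day 0 libraries on both days, so the split does not remove the effect of shared controls.

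**Figure D1:**
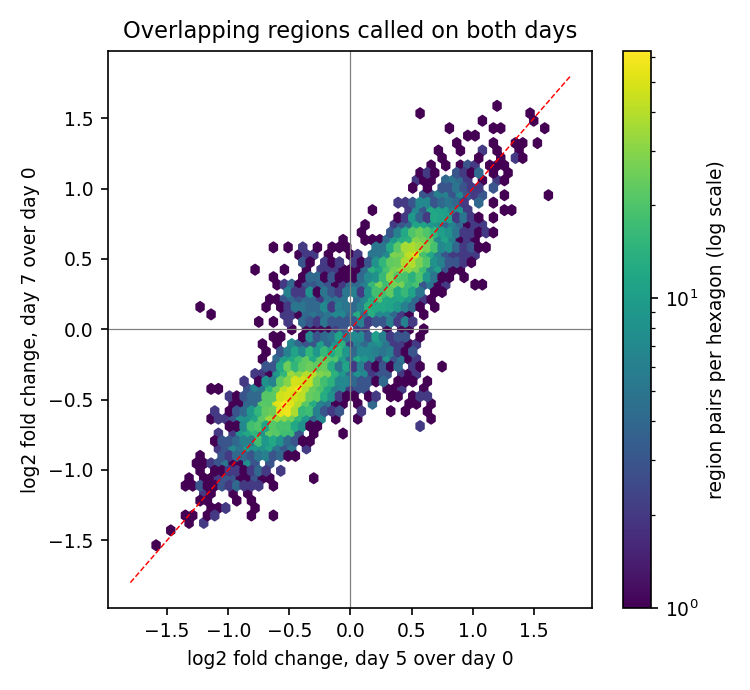
Log2 fold change of normalised H3K9ac reads at day 5 (x axis) and day 7 (y axis), each over day 0, for the 5856 overlapping region pairs called on both days in the authors' deposited table. Colour gives the pairs per hexagon on a log scale and the dashed line marks equal change; most pairs lie near that line (r = 0.902) and 553 lie in the quadrants of opposite direction.

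The strongest changes held on both days included 5 gained and 5 lost regions. On chromosome 2, the region from 4441401 to 4445000 rose 3.03-fold at day 5 (log2 1.60, SE 0.09, limma adjusted p = 0.0003), and its counterpart from 4441501 to 4445100 rose 2.63-fold at day 7. On chromosome 12, the region that starts at 13159401 rose 2.77-fold at day 5 and 2.87-fold at day 7. The chromosome 11 region that starts at 4987601 rose 2.87-fold and 2.75-fold, although its day 0 replicates differed (393 and 297 normalised reads). Regions on chromosome 14 from 8085401 to 8089400 and on chromosome 1 from 17556501 to 17558700 rose 2.67-fold and 2.53-fold at day 5. The largest loss on both days lay on chromosome 19 from 11045401 to 11047900. It fell 3.06-fold at day 5, from 1278 ± 83.2 to 418 ± 35.4 normalised reads (SD, n = 2 each), and 2.87-fold at day 7, from 1172 ± 74.6 to 408 ± 40.7 (SD, n = 2 each), with limma adjusted p-values of 0.00029 and 7.7e-07. Chromosome 1 from 27932601 to 27935200 fell 2.78-fold and 2.65-fold. Chromosome 1 from 9362401 to 9363700, chromosome 15 from 7255301 to 7257400 and chromosome 18 from 1292001 to 1294100 fell between 2.46-fold and 2.63-fold on both days.

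**Figure D2:**
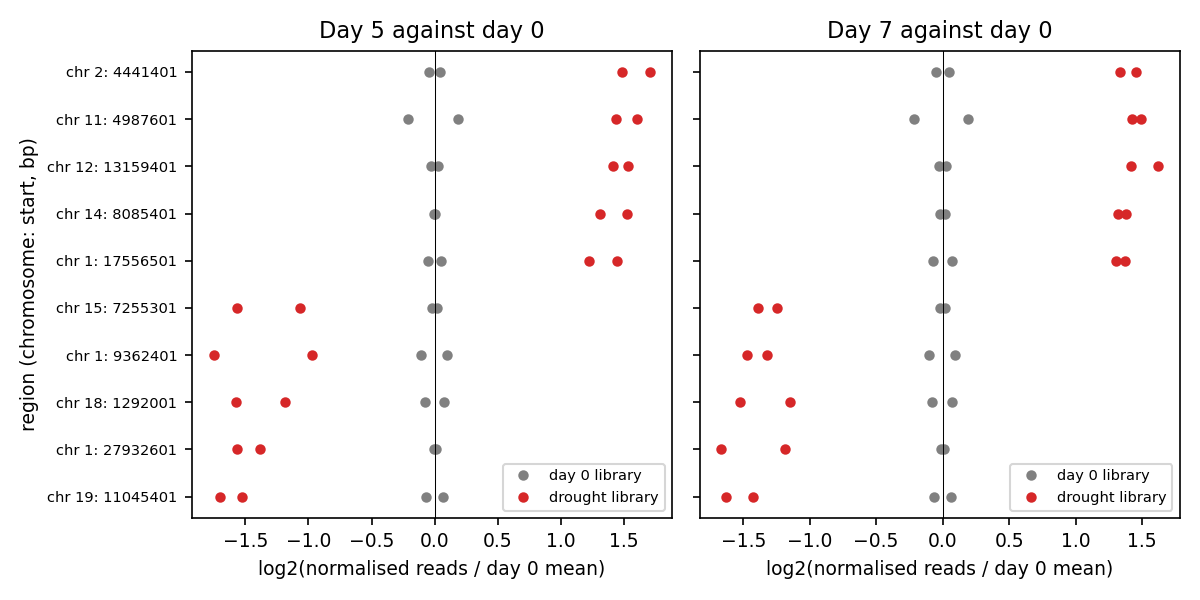
Normalised H3K9ac reads of each library over the day 0 mean, on a log2 scale (x axis), in the 10 regions with the strongest change held on both days (y axis: chromosome and start in bp of the day 5 region), with day 5 on the left and day 7 on the right. Each point is a library, grey for day 0 and red for drought; in all 10 regions both drought libraries lie on a single side of both day 0 libraries.

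No difference between mild and severe drought was detected in the regions where it was tested. A direct limma comparison of day 7 with day 5 was made in the 593 regions of identical coordinates, which had been listed against day 0 on both days. It called 0 regions at an adjusted p of 0.05, with a smallest adjusted p of 0.285. At an unadjusted p of 0.05 it called 59, where 29.6 are given by chance. Identical coordinates arise where the same windows passed on both days, so this set favours regions that changed alike. Of the 593, 583 (98.3%) had a single direction on both days, against 90.6% of all overlapping pairs. Without day 5 replicate 1 the comparison called 10 regions. The median SE of the difference was 0.09 on the log2 scale, and in data simulated for this comparison limma recovered 48.5% of changes of 0.3 and 90.9% of changes of 0.5 on that scale. Differences under about 0.3 were therefore often not detectable, and regions listed on a single day were outside this test. The largest absolute difference among the 593 regions was 0.65. Across the overlapping pairs, the median of the day 7 minus day 5 log2 fold change was 0.01 in pairs gained on both days (interquartile range -0.10 to 0.12) and 0.00 in pairs lost on both days. These pairs were selected for a single direction on both days and the tables were scaled separately, so these medians are no test of a difference.

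Changes were spread over all 19 chromosomes. Called regions per Mb ran from 15.0 to 37.3 at day 5 and from 16.9 to 42.2 at day 7, lowest on chromosome 19 on both days. The share of gained regions ran from 40.3% to 53.6% by chromosome at day 5 and from 38.4% to 56.0% at day 7, lowest on chromosome 15 on both days. None of the 38 shares passed an exact circular-shift test after Benjamini-Hochberg adjustment, with the smallest adjusted p at 0.171 for chromosome 15 at day 7 and 0.792 at day 5.

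Neighbouring regions changed together. This was tested after the regions had been seen. Of 1741 neighbouring pairs of called regions within 5 kb at day 5, 73.7% changed in a single direction, against 50.3% when directions were permuted, and of 2291 such pairs at day 7, 67.4% did, against 50.2%. Both permutation p-values were 1e-05, the smallest that 100000 permutations can give. They concern the order of directions along the genome in these libraries, since regions are not independent replicates of a day. Direction also differed with enrichment over input, and whether neighbours of like enrichment account for the excess was not tested. Overlapping neighbours, 104 at day 5 and 146 at day 7, were left out. All of them went in opposite directions, so leaving them out raises the shares given here. The share fell with distance, from 80.4% under 1 kb to 55.3% at 20 to 50 kb at day 5. The longest runs at day 5 held 6 gained regions on chromosome 10 from 20692001 to 20709600 with a median log2 change of 0.61, and 6 gained regions on chromosome 13 from 5562301 to 5584400 with a median of 0.52. The others of that length were lost, on chromosome 2 from 2871301 to 2890800 (median -0.47) and on chromosome 6 from 24604001 to 24624100 (median -0.33). A shorter run of 5 lost regions on chromosome 2 from 24635001 to 24656100 had a median log2 change of -0.78 and held the region from 24638201 to 24641000, which fell 2.41-fold. At day 7, 6 gained regions on chromosome 10 from 13380101 to 13399600 had a median of 0.60 and 6 lost regions on chromosome 15 from 11702101 to 11720000 a median of -0.43. The medians of these runs come from the authors' deposited table, and the runs were chosen after their values were seen.

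**Figure D3:**
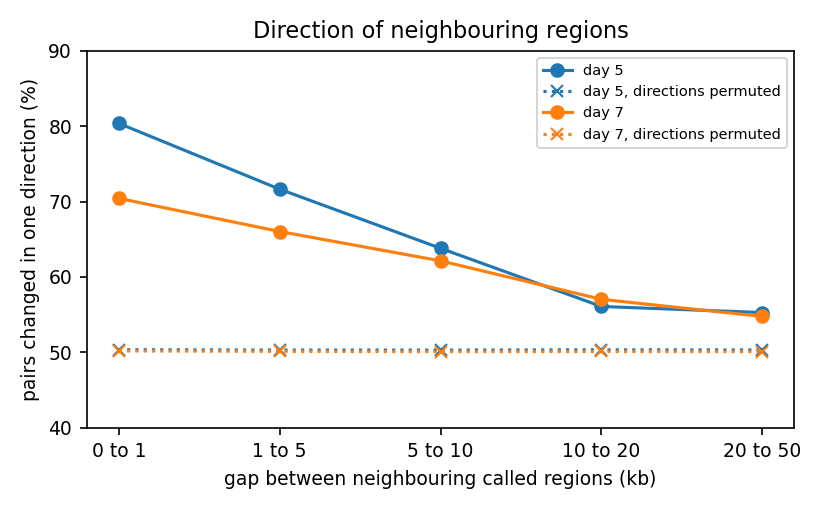
Share of neighbouring called regions that changed in a single direction (y axis, %, starting at 40) by the gap between them (x axis, kb), at day 5 and day 7, with the mean of 100000 permutations of the directions as dotted lines. The observed share falls from 80.4% to 55.3% at day 5 and from 70.4% to 54.8% at day 7, while the permuted share stays between 50.1% and 50.4%.

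Direction also differed with the enrichment of H3K9ac over input, in classes set after the data were seen. At day 5, regions gained in the authors' deposited table made up 16.2% of the 345 called regions with an enrichment of 0.5 to 1, 40.8% of those at 1.5 to 2 and 74.3% of the 1025 regions at 3 or more. At day 7 the share was 34.5% of 148 regions at 0.5 to 1, 50.2% at 1.5 to 2 and 54.3% of 541 regions at 3 or more. A small class with fewer immunoprecipitated reads than 0.5 times the input behaved differently. It was gained in 156 of 159 regions (98.1%) at day 5 and in 112 of 113 (99.1%) at day 7, with median log2 changes of 0.66 and 0.49 in the authors' deposited table.

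**Figure D4:**
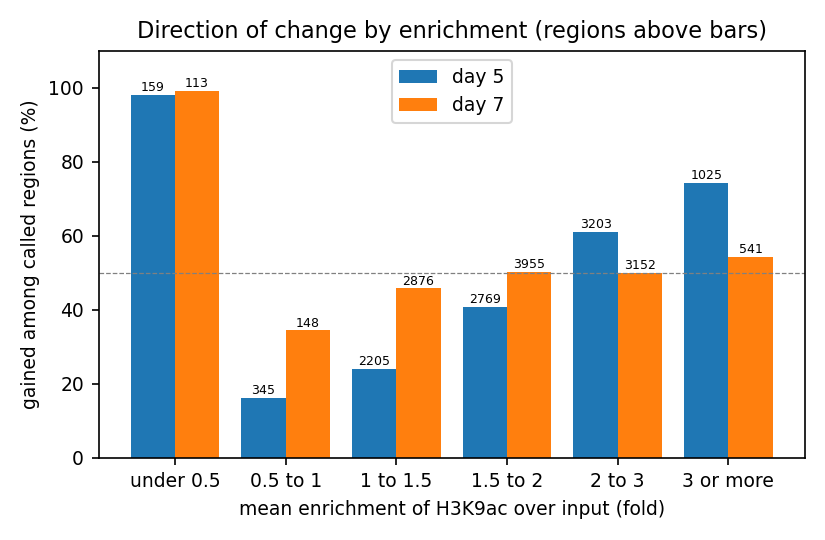
Share of gained regions (y axis, %) among the regions called at day 5 and day 7, by mean enrichment of immunoprecipitated over input reads (x axis, fold), with the number of called regions above each bar and a dashed line at 50%. At day 5 the share rises from 16.2% at 0.5 to 1 to 74.3% at 3 or more, and the class under 0.5 is gained in 98.1% of regions at day 5 and 99.1% at day 7.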

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

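The test of library slopes in this part was set before its result was seen, and the other tests were chosen after.

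In 231 overlapping pairs both day 5 libraries lay above and both day 7 libraries below day 0, and in 216 pairs the reverse held. These differences between the days were not tested, except in 4 pairs of identical coordinates. Of the 593 regions of identical coordinates, 10 went in opposite directions, and the limma comparison of day 7 with day 5 called 0 of these 10 at an adjusted p of 0.05 and 6 at an unadjusted p of 0.05, in regions picked for that difference. In 34 regions at day 5 and 12 at day 7 the input, which the comparisons do not use, exceeded the day 0 input at least 2-fold relative to the median, and in 101 and 1 it was at least 2-fold lower. Of the regions with a higher input, 12 of the 34 called at day 5 and 11 of the 11 called at day 7 were gained.

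Regions with fewer immunoprecipitated reads than 0.5 times the input were nearly all gained on both days (98.1% and 99.1%). A higher general background in the drought libraries would tend to raise the next class of enrichment, 0.5 to 1, as well. That class was gained in 16.2% of regions at day 5 and 34.5% at day 7. Above an enrichment of 0.5, however, the share of gained regions at day 5 fell towards lower enrichment. Something else may thus have lowered that class, so its share does not decide and a higher background stays open. More copies of these sequences in the drought DNA would raise the input by about as much as the immunoprecipitate. The median input change was 0.16 on the log2 scale at day 5 against 0.66 in the immunoprecipitate, and -0.51 at day 7 against 0.49. Input changes are relative to the median listed region, while the immunoprecipitate follows the scaling of the deposited values. On these scales more copies cannot be the whole cause. Repeats or organelle DNA carried along in the immunoprecipitation, and acetylation that changes with drought, stay open and were not tested.

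At day 5 the share of gained regions rose with enrichment over input. The day 5 input is part of that enrichment. Its median log2 change was 0.41 in the class of 0.5 to 1 and -0.21 at 3 or more. With enrichment over the day 0 input alone the share still rose, from 16.5% at 0.5 to 1 to 69.4% at 3 or more. Immunoprecipitation efficiency that differs between libraries could give such a trend. Over 9547 called regions of an enrichment of at least 0.5, log2 reads over the day 0 mean rose by 0.28 and 0.39 per log2 of enrichment in the 2 day 5 libraries. The day 5 slopes differed by 0.10, less than their mean of 0.33, so that efficiency shared by both day 5 libraries cannot be told apart from an effect of day 5, since no spike-in or further day 5 library was analysed here.

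Neighbouring regions changed in a single direction more often than permuted ones. Broad regions broken into pieces by the window threshold could give this. At gaps of 20 to 50 kb the share was 55.3% (50.3% permuted) at day 5 and 54.8% (50.1% permuted) at day 7. These gaps exceed the longest listed regions of 19500 bp (day 5) and 14200 bp (day 7). Listed regions may themselves be pieces of longer ones, so their length sets no bound and these shares do not decide. At shorter gaps, such as 5 to 10 kb with shares of 63.8% and 62.1%, broken regions cannot be told apart from separate ones either. Regional changes of the input DNA would remove most of the excess within 5 kb, but after correction for the input the share was 68.4% at day 5 and 63.9% at day 7, so the input is not the whole cause. That drought changes H3K9ac over domains larger than a region is a hypothesis that stays open, as is a role of genes lying close together, which was not tested without gene positions.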

How the results depend on the processing

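Alternatives named here as added were chosen after seeing the data: limma, recomputed enrichment, direction relative to input, omission of input-dominated regions, identical coordinates and separate day 0 libraries. Counts of gained and lost regions on both days stayed within 1.5 times at an adjusted p of 0.001, relative to the input, without input-dominated regions and with limma. A log2 change of at least 1 left 92 gained and 84 lost at day 5 and 110 and 81 at day 7, and 43, 41 and 0 pairs gained, lost and opposite on both days, fewer by construction. A deposited enrichment of at least 2 in the group with more reads left 2921 and 2683 at day 5 and 2484 and 3493 at day 7, a recomputed enrichment of at least 2 (added) left 2719 and 1509 and 1871 and 1822, and unscaled reads gave 3453 gained at day 7. Opposite pairs numbered 260 at a reciprocal 50% and 236 with limma, and r was 0.971 in regions of identical coordinates. The cause of these last 3 was not tested. Leaving out each replicate in turn gave limma counts of 2836 to 4040 gained and 3166 to 4586 lost at day 5, lowest without day 0 replicate 1, 4205 to 4881 and 4120 to 4931 at day 7, and 0 to 10 for day 7 against day 5, where 10 came without day 5 replicate 1. The lone library is assumed to vary like the other groups. The region on chromosome 17 from 3917401 to 3918600 turned to -0.98 at day 7 relative to the input, which was higher there by 2.36. The minimum of 20 reads removed no region and tests nothing. For named regions, 225 of 225 limma values kept their direction, and so did 89 of 90 values with no test. These regions were picked for extreme changes in the same libraries, so a reversal was unlikely from the start. The other 60 summary values stayed within the tolerance for their kind, 1.5 times for a count. Samples with equal replicate numbers share a number alone. With the replicate as a block limma called 4121 gained and 4618 lost at day 5 and 5007 and 5089 at day 7, against 4185, 4699, 5005 and 5086 without it, and 0 at day 7 against day 5. Deviations of equally numbered libraries correlated at 0.108 and 0.094. The planned count models, gene lists, gene positions, motif and counts of genes were not run. Depth was not varied. In simulated data, log2 changes of 0.3 were recovered in 27.9% of the regions given that change at day 5 and 57.4% at day 7. Far fewer regions were changed there than limma called in the real data, and all had a single dispersion. These shares therefore do not give the recovery of limma in the listed regions.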

Other observations

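The regions named in this part were chosen after their values were seen. Among the 4950 overlapping pairs that shared at least 50% of each region, 260 changed in opposite directions on the 2 days, with median absolute log2 changes of 0.18 at day 5 and 0.16 at day 7 in the authors' deposited table, against 0.50 on both days in the other pairs. A few opposite pairs were larger. On chromosome 7, the region from 10035501 to 10037300 rose at day 5 from 413 ± 28.8 to 632 ± 29.7 normalised reads (SD, n = 2 each; log2 0.61, SE 0.08, limma adjusted p = 0.00098). The overlapping region from 10034701 to 10036900 fell at day 7 from 558 ± 61.3 to 379 ± 12.2 (SD, n = 2 each; log2 -0.55, SE 0.09, limma adjusted p = 0.00019). On chromosome 12, the region from 13956401 to 13958100 rose at day 5 (log2 0.65, SE 0.12, limma adjusted p = 0.0024) and that from 13956101 to 13957300 fell at day 7 (log2 -0.56, SE 0.10, limma adjusted p = 0.00043). On chromosome 5, the region from 4466701 to 4467800 rose at day 5 (log2 0.52, SE 0.08, limma adjusted p = 0.0016), and that from 4466401 to 4467400 fell at day 7 (log2 -0.36, SE 0.07, limma adjusted p = 0.0008). The opposite order was seen on chromosome 18, where the region from 12986301 to 12987300 fell at day 5 (log2 -0.65, SE 0.20, limma adjusted p = 0.019) and that from 12985601 to 12987200 rose at day 7 (log2 0.36, SE 0.08, limma adjusted p = 0.0011). The intervals of a pair differ, the tables were scaled separately and the difference between days was not tested in these regions.

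The longest run of regions changed in a single direction at day 7 held 7 gained regions on chromosome 10 from 883101 to 900800, with a median log2 change of 0.26 in the authors' deposited table. On chromosome 19, 6 regions from 14513501 to 14529900 were gained at day 7 with a median of 0.55 in the authors' deposited table. On chromosome 2, 5 regions from 18348701 to 18369400 were gained at day 5 with a median of 0.91, and a range of 0.81 to 0.95, in the authors' deposited table.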
